A study of Caenorhabditis elegans with 10 samples.

How the data were processed

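Whole-worm RNA was sequenced from 10 samples of Caenorhabditis elegans, 5 of strain N2 and 5 of strain F01D4.5(baf20), grown for 48 hours after L1 arrest at 20 °C. Per the labels' protocols, RNA was extracted with QIAzol and the miRNeasy kit, libraries were made with the Illumina TruSeq Stranded mRNA kit, and sequencing ran on an Illumina HiSeq instrument. The submitters' processing notes name CASAVA, HISAT2, HTSeq and DESeq2, without versions, and the genome builds ce10 and ce11, without saying which was used for counting. The strand setting of the counting is not given in the sources used here. The series' design text calls the 5 samples of each strain biological replicates.

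The authors deposited 1 table per sample with whole-number counts, not normalized, for 57827 rows. Rows are named by transcript in most cases, so that a gene with several isoforms has several rows. Names of 57515 rows, which held 99.78% of counts, matched gene, transcript or sequence names of the Ensembl release 115 annotation on WBcel235. The counts of all rows of a gene were summed to 46748 genes. Gene symbols came first from the RefSeq gene table, also on WBcel235. No row held reads without a gene. Of the genes, 5541 (11.9%) had more than 1 row, and these held 7.14% of all counts. Protein-coding genes with more than 1 row had a median of 0.657 CPM, those with 1 row 4.87 CPM. Reads that fit several isoforms appear to be largely missing from the deposited counts of such genes: unc-54, the main body wall myosin gene, held 8 to 29 counts per library. Fold changes of these genes rest on the reads that tell their isoforms apart. Coordinates are those of WBcel235, counted from 1. Genes that share reads with near-identical copies were not separated further.

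The total count per library was 9059910 to 11056979, and 3 counts corresponded to 0.271 to 0.331 CPM. Intervals and such floors cover counting error only. The 5 libraries of each strain were treated as replicates after all pairs within a strain had been compared by a chi-square of their counts. F01D4.5(baf20) replicates 1 and 2 were the closest pair, with a chi-square per degree of freedom of 2.20 where the other pairs gave 5.85 to 129. They differed by more than counting error, which does not show that they are independent samples of worms. They were kept as separate samples, with their sum tried as an alternative.

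Strains were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the strain as group (minimum count 10, minimum total count 15), libraries were scaled by TMM, and dispersions and the quasi-likelihood model were fitted with robust estimation and the strain as the only term. The test was two-sided, and p was adjusted by the Benjamini-Hochberg method over 12332 genes with a threshold of 0.05. The common biological coefficient of variation was 0.325. CPM values are counts per 1e6 of the TMM-scaled library sizes, and log2 CPM a prior count of 2. Fold changes are those of the fitted model.

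50 gene lists for tissues, stages, stress responses, metabolism and housekeeping complexes were written before the data were examined, as were the test, the rule for named genes and the first group of alternatives below. Lists with at least 3 tested members (48 of 50) were tested with limma's camera (limma 3.58.1) on voom values with a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. The rule named F01D4.5, up to 12 genes per direction with the largest log2 fold change among changed genes with a mean log2 CPM of at least 2 and no overlap between strains, up to 4 genes with the smallest adjusted p from each list past the set test or with at least 3 changed members, up to 5 changed genes within 1 Mb of F01D4.5, and the 5 genes with the smallest p. The share of changed genes within 1 Mb of F01D4.5 was compared with that of all other genes by Fisher's exact test.

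The procedure was tested on simulated counts for the comparison of F01D4.5(baf20) with N2, drawn for 12332 genes from the observed means, dispersions and library sizes with 200 genes changed. It recovered 2% of genes changed 1.5-fold, 32% of those changed 2-fold, 78% of those changed 4-fold and 94% of those changed 8-fold, with 3.74% of calls false. In these data genes vary independently, unlike in real worms, and 0 lists were called when no gene was changed.

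Alternatives set beforehand were DESeq2 1.42.0, its size factors and upper-quartile factors in edgeR, no filter on low counts, a filter of at least 5 CPM in 5 samples (by library totals without TMM scaling), the replicate number as a block, removal of yolk, sperm protein and collagen genes, removal of each library in turn, and windows of 0.5 and 2 Mb. Alternatives chosen after seeing the data were the rows as deposited, removal of both libraries numbered 5, the sum of F01D4.5(baf20) replicates 1 and 2, 2 surrogate variables from sva 3.50.0, and removal of rRNA genes. As a check against chance, 100 of the 126 splits of the 10 libraries into 5 and 5 were drawn with the split by strain among them, and each was tested in the same way. Labels were checked by setting each library against the other 9 on the genes called without it. Figures were drawn with matplotlib 3.10.9. GC content was not examined, since no genome sequence was used here.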

Results

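Messenger RNA was sequenced from whole Caenorhabditis elegans of 2 strains. N2 is the standard laboratory wild type. The other strain carries the designation F01D4.5(baf20), after the gene F01D4.5, and the labels do not say what the change in that gene is. Worms hatched into L1 arrest were grown on plates with OP50, an Escherichia coli strain used as food, for 48 hours at 20 °C, and 1000 to 2000 worms were collected per sample. Each strain had 5 biological replicates, which gave 10 libraries. The total count per library lay between 9059910 (N2 replicate 3) and 11056979 (N2 replicate 4). After rows were summed per gene, 12332 genes held enough counts to be tested. The design gives a single comparison, which asks what differs in the transcriptome of F01D4.5(baf20) worms relative to N2.

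F01D4.5, the gene in the strain's name, was 3.34-fold lower in F01D4.5(baf20) worms than in N2. Its level fell from 10.8 ± 2.93 CPM (counts scaled to library size) in N2 to 3.23 ± 0.738 CPM in F01D4.5(baf20) (SD, n = 5 each). All 5 F01D4.5(baf20) libraries, at 2.15 to 4.03 CPM, lay below all 5 N2 libraries, at 6.44 to 14.4 CPM, so that no library contradicted its label. The log2 fold change was −1.74 (SE 0.241, adjusted p = 0.0264, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The gene lies on the minus strand of chromosome IV at 10482624 to 10483657 (WBcel235). Its transcript F01D4.5b held 538 of the N2 counts and 159 of the F01D4.5(baf20) counts, and F01D4.5a held 12 and 3. As the gene is counted in these 2 rows, its level may leave out reads that the isoforms share. The fold change thus rests mostly on reads assigned to F01D4.5b. With any 1 of 8 libraries left out (replicates 1 to 4 of either strain) the adjusted p by edgeR rose to between 0.0853 and 0.130, while the log2 fold change over all 10 such fits stayed between −1.88 and −1.61. Transcript remained detectable in every F01D4.5(baf20) library, where 3 counts correspond to 0.272 to 0.321 CPM. Reads were not examined by position within the gene, so that a lower transcript level was not distinguished from sequence missing in the allele.

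Besides F01D4.5, 7 further genes changed, 4 of them higher and 3 lower in F01D4.5(baf20) worms. The steepest decrease was that of T27E7.1, a protein-coding gene on chromosome IV (14519759 to 14520999), which fell 15.4-fold, from 194 ± 35.3 to 12.62 ± 3.57 CPM (SD, n = 5 each). Among the genes that rose, F57A10.2 on chromosome V (15766575 to 15767274) went from 0.948 ± 0.214 to 6.44 ± 1.33 CPM, a 6.71-fold increase. Y71A12B.8 on chromosome I (13938810 to 13942016) was nearly silent in N2, with 5 counts over the 5 N2 libraries against 63 in F01D4.5(baf20). The ratio scaled to library size was 12.9 (95% exact binomial interval 5.26 to 41.2, which covers counting error only). This gene falls outside the rule for named genes and was chosen after its values were seen. Near-identical copies of T27E7.1 and F57A10.2, with which reads could be shared, were not searched for.

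The other 4 genes changed by less than 2-fold. pph-7, which encodes a predicted serine/threonine protein phosphatase, rose 1.99-fold from 22.3 ± 3.03 to 44.5 ± 3.11 CPM. set-10, which encodes a SET-domain protein, rose 1.81-fold from 11.4 ± 0.674 to 20.7 ± 1.72 CPM. Y82E9BR.22 fell 1.78-fold from 42.5 ± 5.29 to 23.9 ± 0.986 CPM, and the pseudogene Y17D7C.3 fell 1.79-fold from 15.88 ± 1.103 to 8.85 ± 0.679 CPM. pph-7 and set-10 lie on chromosome I at 2903635 to 2907757 and 15027713 to 15030708. Y82E9BR.22 lies on chromosome III at 1406461 to 1409239 and Y17D7C.3 on chromosome V at 18720589 to 18723771. Both pph-7 and set-10 overlap a gene on the opposite strand (parp-1 and F33H2.2), and since the strand setting of the counting is not given in the sources used here, reads of such pairs cannot be assigned with certainty.

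**Figure D1:**
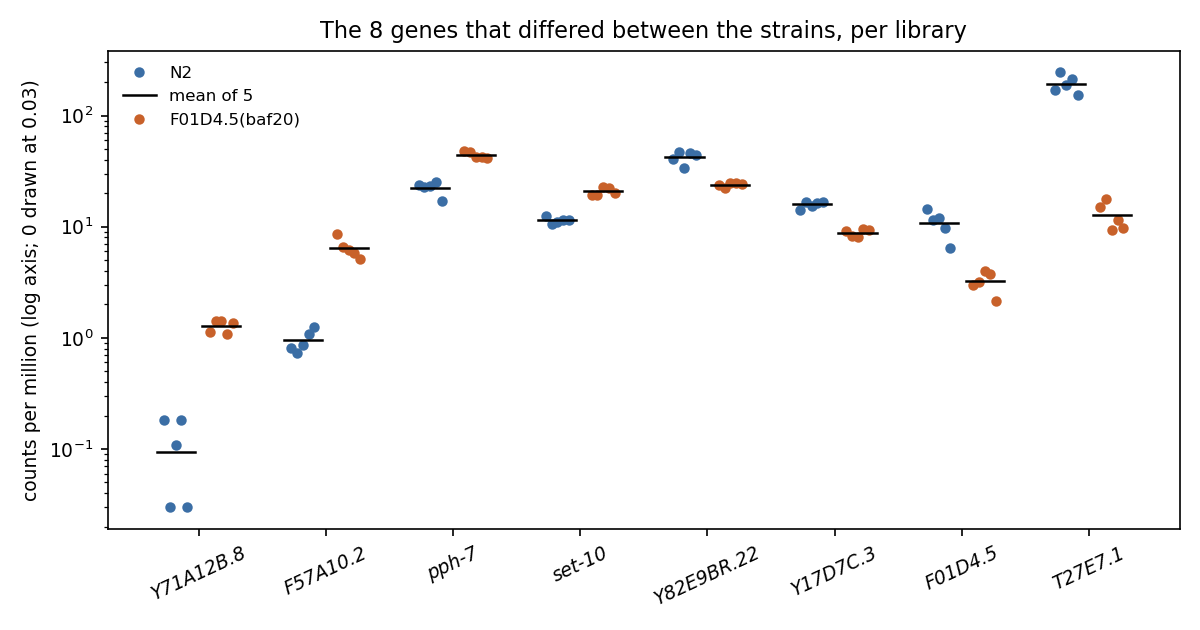
CPM on a log axis of the 8 genes that differed between the strains, with 1 point per library (blue, N2; orange, F01D4.5(baf20)) and a black line at the mean of 5. A value of 0 is drawn at 0.03. In each gene the 5 libraries of one strain lie apart from the 5 of the other, as for T27E7.1 (154.5 to 243.9 CPM in N2 against 9.37 to 17.6 CPM).

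In all, 8 of the 12332 genes tested passed the threshold in edgeR's quasi-likelihood test, 4 higher and 4 lower. Their log2 fold changes and adjusted p by edgeR were −3.94 (SE 0.214, adjusted p = 1.51e-05) for T27E7.1, 2.75 (SE 0.224, adjusted p = 0.000549) for F57A10.2, 3.54 (SE 0.481, adjusted p = 0.0253) for Y71A12B.8 and 0.99 (SE 0.122, adjusted p = 0.0222) for pph-7. For set-10, Y17D7C.3 and Y82E9BR.22 they were 0.86 (SE 0.109, adjusted p = 0.0222), −0.84 (SE 0.114, adjusted p = 0.0253) and −0.83 (SE 0.113, adjusted p = 0.0253). At an unadjusted p under 0.05 there were 710 genes, 434 higher and 276 lower. In 98 genes all F01D4.5(baf20) values lay above all N2 values and in 80 below, together 1.44% of the genes tested, where chance gives 0.794%. T27E7.1 and F57A10.2 passed in each of the 10 fits with 1 library left out, in which the total of changed genes ranged from 2 to 13, whereas the other 6 genes each lost the call in 8 or 9 of these fits. Their log2 fold changes moved little in them, with 0.91 to 1.04 for pph-7, 0.81 to 0.89 for set-10, −0.90 to −0.81 for Y17D7C.3, −0.91 to −0.79 for Y82E9BR.22, 3.26 to 3.87 for Y71A12B.8 and −1.88 to −1.61 for F01D4.5. DESeq2 called 33 genes on the same table, and these included all 8. With F01D4.5(baf20) replicates 1 and 2, the closest pair of libraries, summed, edgeR called T27E7.1 and F57A10.2 alone.

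In edgeR's test on all 10 libraries with the strain as the only term, no other gene within 1 Mb of F01D4.5 changed. DESeq2's test called more than F01D4.5 there, with a share of 0.578% (Fisher's exact test, p = 0.237). The highest share over the 23 alternatives, other window sizes included, was 1.16%. Within 1 Mb of F01D4.5, the share of changed genes was 0.289% (1 of 346, F01D4.5 itself), against 0.0584% (7 of 11986) elsewhere (Fisher's exact test, two-sided, p = 0.204). As F01D4.5 defines the window, this share rests on that gene alone. Without it, 0 genes of the window were called in that test, unlike in DESeq2's. The neighbouring gene egl-21, which encodes a carboxypeptidase that processes neuropeptides, had 10.9 ± 3.29 CPM in N2 and 9.10 ± 1.62 CPM in F01D4.5(baf20). Its log2 fold change was −0.26 (SE 0.214, adjusted p = 0.927 by edgeR). egl-21 is counted in 3 transcript rows, so its level may also leave out shared reads. ced-5, a regulator of cell-corpse engulfment on the other side, had 191.7 ± 37.95 and 213.6 ± 27.5 CPM (log2 fold change 0.16, SE 0.151, adjusted p = 0.930 by edgeR).

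The main variation among the 10 libraries did not follow the strain. The first principal component held 56.2% of the variance of log2 CPM and set the libraries numbered 5 of both strains (76.0 for N2 and 66.9 for F01D4.5(baf20)) apart from the other 8, which lay between −40.9 and 8.0. The second held 16.9% and set F01D4.5(baf20) replicates 1 and 2 (−40.3 and −41.1) apart. None of the first 4 components separated the strains.

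**Figure D2:**
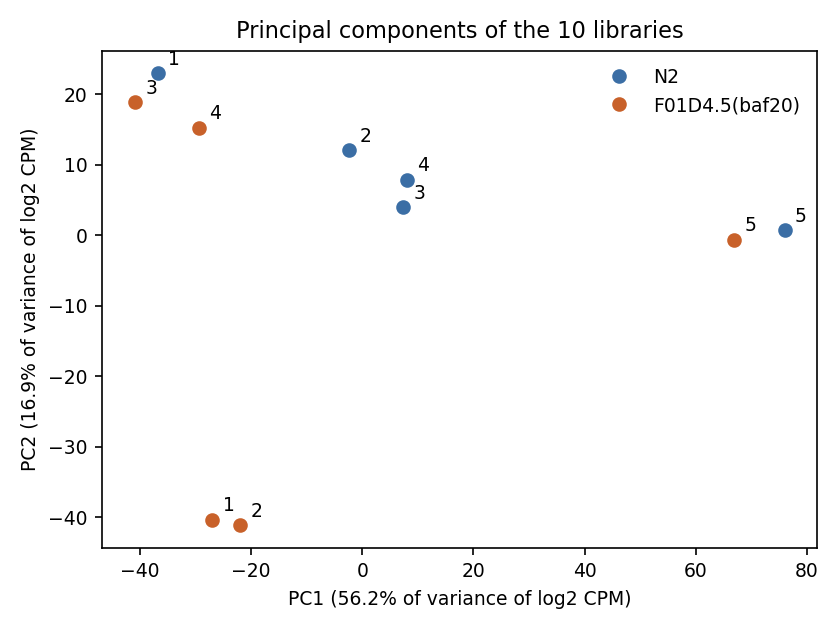
First and second principal components of the log2 CPM values of 12332 genes, 1 point per library with its replicate number (blue, N2; orange, F01D4.5(baf20)). The libraries numbered 5 lie at 76.0 and 66.9 on the first component, away from the other 8.

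With the preset correlation of the set test, cuticle collagen genes lay lower in F01D4.5(baf20) worms as groups, though no single collagen gene changed. The correlation estimated from the data was 0.879 for the furrow and annular list, 0.465 for the L4 and adult list and 0.242 for the col family. With it, none of these lists passed. All 11 tested furrow and annular collagens, which build the ridged pattern of the cuticle, had negative log2 fold changes, with a median of −1.27 (camera adjusted p = 4.24e-05 with a preset correlation, adjusted p = 0.849 with an estimated correlation). Examples were dpy-7 with 11.8 ± 16.3 CPM in N2 and 3.61 ± 4.60 CPM in F01D4.5(baf20), and dpy-17 with 8.86 ± 1.38 and 6.05 ± 1.24 CPM (SD, n = 5 each). The 8 collagens of the L4 and adult cuticle also all had negative values, with a median of −1.05 (camera adjusted p = 0.0175, adjusted p = 0.849 with an estimated correlation). Of these, bli-1, a strut collagen, had 42.7 ± 43.6 and 16.3 ± 19.9 CPM. In the wider col family, 74 genes were negative and 30 positive, with a median of −0.29 (camera adjusted p = 0.000103, adjusted p = 0.849 with an estimated correlation). Its members col-81 and col-92 had log2 fold changes of −0.34 (SE 0.134) and −0.37 (SE 0.156), with adjusted p by edgeR of 0.799 and 0.835.

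By their medians, moulting genes and signalling families of the epidermis lay on the same side. Of 10 moulting genes, 9 were negative, with a median of −0.56 (camera adjusted p = 0.0175, adjusted p = 0.849 with an estimated correlation). mlt-10, a gene needed for moulting, had 37.6 ± 31.6 CPM in N2 and 12.2 ± 12.4 CPM in F01D4.5(baf20), and noah-2, a component of the apical extracellular matrix, had 35.01 ± 35.1 and 19.04 ± 16.7 CPM. Among hedgehog-related and patched-related genes, 39 of 49 were negative, with a median of −0.25 (camera adjusted p = 0.0184, adjusted p = 0.849 with an estimated correlation). The 4 members with the smallest p all lay the other way. These were grl-17, ptc-2, ptr-13 and ptr-22, with log2 fold changes of 1.85, 0.545, 0.35 and 0.89. At an unadjusted p under 0.05 by edgeR, 2 members were higher and 0 lower. grl-17 had 0.450 ± 0.163 CPM in N2 and 1.66 ± 0.335 CPM in F01D4.5(baf20). Its adjusted p by edgeR was 0.0666 over all genes, and it was the 1 gene past the threshold when adjusted over the list alone. DESeq2's test (adjusted p = 0.0133) and edgeR with 2 surrogate variables (adjusted p = 0.0379) called grl-17.

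In the libraries that stood apart, these epidermal lists were high. The mean log2 CPM of the furrow collagens was 6.80 in N2 replicate 5 and 5.73 in F01D4.5(baf20) replicate 5, against 2.095 to 4.59 in the other 8 libraries. For the moulting genes it was 5.28 and 4.67 in the libraries numbered 5, against 2.71 to 3.98. With N2 replicate 5 left out, the median of the furrow collagens was −0.27 (camera adjusted p = 0.0102), and the calls of 3 lists ended. These were the L4 and adult cuticle collagens with a median of −0.04 (adjusted p = 0.0830), the moulting genes with −0.06 (adjusted p = 0.183) and the hedgehog-related and patched-related genes, whose median turned to 0.11 (adjusted p = 0.4999). The median of the col family also turned, to 0.20, although its test still pointed down (adjusted p = 0.0393). The same 3 calls ended without F01D4.5(baf20) replicate 3 (adjusted p = 0.0722, 0.0722 and 0.0756), and that of the hedgehog-related list also without F01D4.5(baf20) replicate 1 or 4 (adjusted p = 0.0936 and 0.108). Without F01D4.5(baf20) replicate 5 the medians were −2.86 for the furrow collagens, −2.83 for the L4 and adult cuticle collagens, −0.59 for the col family, −1.08 for the moulting genes and −0.63 for the hedgehog-related list. Without both libraries numbered 5 all 5 lists passed at the preset correlation and none with an estimated correlation (adjusted p = 0.762 each), with medians of −1.58 for the furrow collagens (adjusted p = 4.07e-06), −1.80 for the L4 and adult cuticle collagens (adjusted p = 0.00485), −0.46 for the col family (adjusted p = 3.17e-06), −0.73 for the moulting genes (adjusted p = 0.00485) and −0.26 for the hedgehog-related list (adjusted p = 0.00117). The hedgehog-related list did not pass with 2 surrogate variables (median −0.09, adjusted p = 0.213) or with DESeq2's statistics (−0.26, adjusted p = 0.134), and lost its call in 8 of 23 alternatives. Over all alternatives the camera adjusted p ranged from 3.37e-14 to 0.849 for the furrow collagens, from 6.80e-06 to 0.849 for the L4 and adult cuticle collagens, from 5.89e-05 to 0.849 for the moulting genes, from 1.87e-06 to 0.849 for the hedgehog-related list and from 1.04e-09 to 0.849 for the col family.

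Lists of sperm formation, oocyte and eggshell, and small RNA pathway genes had positive medians, again without a changed gene, while the list of germline and meiosis genes did not pass (camera adjusted p = 0.0787). Of 41 genes for sperm formation and function, 33 were positive, with a median of 0.15 (camera adjusted p = 0.00370 with a preset correlation, adjusted p = 0.849 with an estimated correlation). ssp-19 had 28.4 ± 4.26 CPM in N2 and 37.7 ± 6.28 CPM in F01D4.5(baf20), and spe-51 had 4.15 ± 0.351 and 5.90 ± 1.47 CPM. F01D4.5(baf20) replicates 1 and 2 had the highest means of this list, at 4.83 and 4.85 log2 CPM, against 4.37 to 4.62 in the other 8 libraries. Among 16 oocyte and eggshell genes, 14 were positive, with a median of 0.22 (camera adjusted p = 0.0466, adjusted p = 0.849 with an estimated correlation). pos-1, a maternal RNA-binding protein, had 500.4 ± 134.8 and 629.5 ± 175.6 CPM, and puf-11, a Pumilio-family RNA-binding protein, 359 ± 90.0 and 444.6 ± 87.4 CPM. The mean of this list was lowest in the libraries numbered 5, at 7.55 in N2 and 7.86 in F01D4.5(baf20), against 8.24 to 8.83 elsewhere. Small RNA pathway genes were positive in 26 of 31 cases, with a median of 0.14 (camera adjusted p = 0.0175, adjusted p = 0.849 with an estimated correlation). alg-5, an Argonaute, had 155.7 ± 33.5 and 210.0 ± 35.2 CPM. Without N2 replicate 5 the calls of all 3 lists ended, with medians of 0.11 for sperm formation (adjusted p = 0.0814), 0.06 for oocyte and eggshell genes (adjusted p = 0.950) and 0.07 for small RNA pathways (adjusted p = 0.507). Without F01D4.5(baf20) replicate 3 the oocyte and eggshell list (median 0.10, adjusted p = 0.487) and small RNA pathways (0.09, adjusted p = 0.112) lost theirs, sperm formation lost its call without F01D4.5(baf20) replicate 2 (0.09, adjusted p = 0.0514), and oocyte and eggshell genes also without N2 replicate 3 or F01D4.5(baf20) replicate 4 (adjusted p = 0.0677 and 0.287). Without both libraries numbered 5 all 3 lists passed at the preset correlation and none with an estimated correlation (adjusted p = 0.762 each), with medians of 0.16 (adjusted p = 0.00141), 0.19 (adjusted p = 0.0184) and 0.12 (adjusted p = 0.0307). With 2 surrogate variables the test of sperm formation pointed down although its median was 0.02 (adjusted p = 0.843), and small RNA pathways did not pass (0.07, adjusted p = 0.112). Oocyte and eggshell genes also lost the call with DESeq2's statistics (adjusted p = 0.0831), upper-quartile factors (adjusted p = 0.0522) and the filter of 5 CPM (adjusted p = 0.0629), in 9 of 23 alternatives in all. Over all alternatives the adjusted p ranged from 0.000167 to 0.849 for sperm formation, from 0.000971 to 0.950 for oocyte and eggshell genes and from 0.000857 to 0.849 for small RNA pathways.

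**Figure D3:**
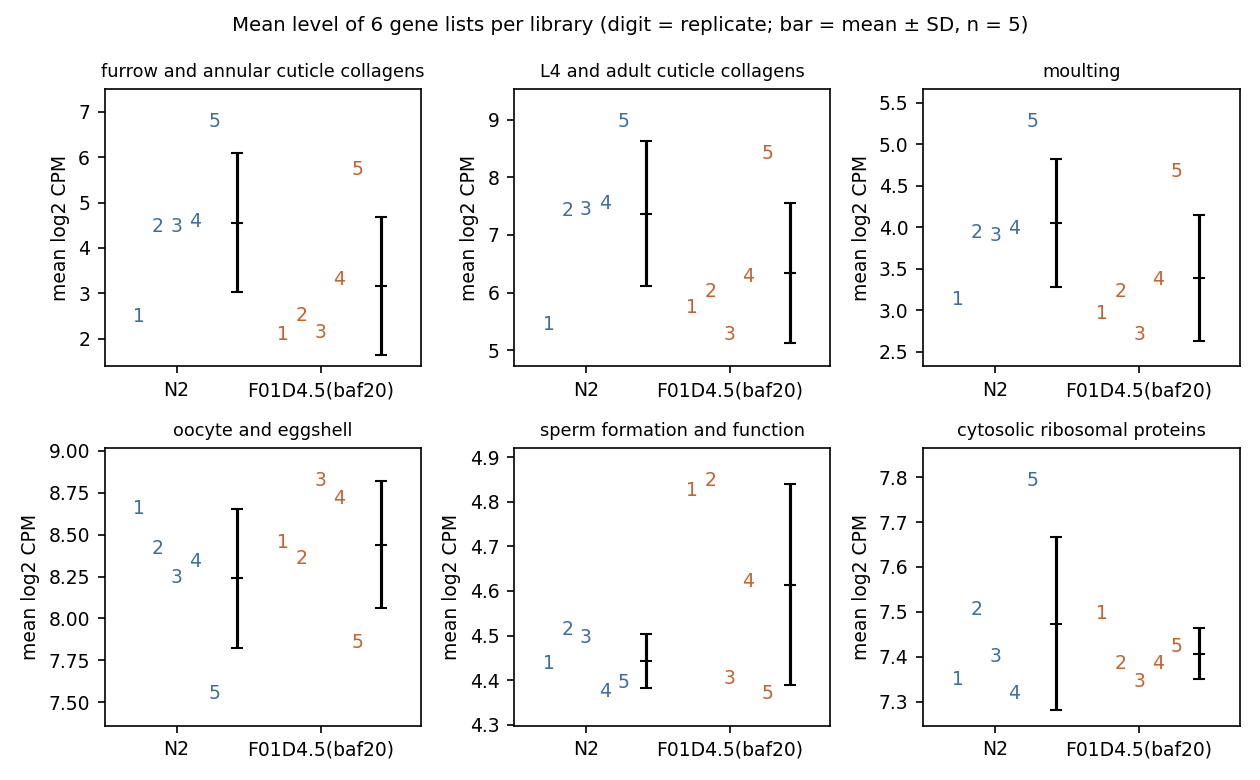
Mean log2 CPM of 6 gene lists in each library, drawn as its replicate number (blue, N2; orange, F01D4.5(baf20)), with the mean ± SD of 5 beside each strain. The libraries numbered 5 have the highest furrow collagen means (6.80 and 5.73) and the lowest oocyte and eggshell means (7.55 and 7.86) of their strains.

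Cytosolic ribosomal protein genes lay slightly lower in F01D4.5(baf20) worms, with 40 of 63 negative and a median of −0.09 (camera adjusted p = 0.0281, adjusted p = 0.849 with an estimated correlation). None passed over all genes, whereas 5 lower and 1 higher passed when adjusted over the list alone. rpl-29 had 201.6 ± 38.3 CPM in N2 and 112.5 ± 11.9 CPM in F01D4.5(baf20) (log2 fold change −0.84, SE 0.139, adjusted p = 0.0784 by edgeR), and rpl-35A had 44.5 ± 9.14 and 25.3 ± 2.004 CPM (−0.82, SE 0.151, adjusted p = 0.152). rpl-31 and rpl-27A, next by p, had log2 fold changes of −0.40 and −0.58. All 4 are counted in several transcript rows, so these levels may leave out reads that their isoforms share. Among all genes counted in several rows, 30 were lower and 11 higher at an unadjusted p under 0.01 by edgeR. For genes with 1 row these were 40 and 83. Whether the lower values of the ribosomal list go back to this was not tested. The call of the list was lost without F01D4.5(baf20) replicate 2, 3 or 5 (adjusted p = 0.0653, 0.0722 and 0.0540) and without N2 replicate 5, where the median was −0.01 and the test pointed up (adjusted p = 0.977). Nor did the list pass without both libraries numbered 5 (−0.04, adjusted p = 0.982), with 2 surrogate variables (−0.05, adjusted p = 0.236), with no filter (−0.07, adjusted p = 0.0924) or with the filter of 5 CPM (−0.09, adjusted p = 0.0629). Over all alternatives its adjusted p ranged from 0.00204 to 0.982.

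Of the remaining lists past the set test, 28 of 46 UDP-glucuronosyltransferases, which conjugate small molecules, were negative, with a median of −0.18 (camera adjusted p = 0.0246, adjusted p = 0.849 with an estimated correlation). ugt-41 had 111.3 ± 9.29 CPM in N2 and 77.3 ± 15.9 CPM in F01D4.5(baf20). Neuropeptide genes were negative in 63 of 84 cases with a median of −0.11 (camera adjusted p = 0.0246, adjusted p = 0.849 with an estimated correlation), among them nlp-11 with 17.2 ± 3.77 and 12.2 ± 2.1 CPM. Pharynx genes were negative in 6 of 7 cases with a median of −0.32 (camera adjusted p = 0.0466, adjusted p = 0.849 with an estimated correlation), among them the troponin C gene tnc-2 with 40.1 ± 10.5 and 32.1 ± 8.03 CPM. Without N2 replicate 5 none of these 3 lists passed, and the medians were 0.01 for UDP-glucuronosyltransferases (adjusted p = 0.4999), 0.06 for neuropeptides (adjusted p = 0.841) and −0.26 for pharynx genes (adjusted p = 0.0993). Nor did they without F01D4.5(baf20) replicate 3 (adjusted p = 0.0722, 0.370 and 0.370), and without both libraries numbered 5 the neuropeptides and the pharynx genes did not pass (adjusted p = 0.179 and 0.129), while UDP-glucuronosyltransferases did at the preset correlation (median −0.23, adjusted p = 0.0225, adjusted p = 0.762 with an estimated correlation). With 2 surrogate variables none of the 3 passed (adjusted p = 0.833, 0.0651 and 0.0651). UDP-glucuronosyltransferases also lost the call without F01D4.5(baf20) replicate 1 (adjusted p = 0.0885), with F01D4.5(baf20) replicates 1 and 2 summed (adjusted p = 0.0508), with DESeq2's statistics (adjusted p = 0.134) and with no filter (adjusted p = 0.0665). Neuropeptides lost it without F01D4.5(baf20) replicate 4 (adjusted p = 0.235) and with no filter (adjusted p = 0.0825). The pharynx list lost it in 14 of 23 alternatives, among them upper-quartile factors (adjusted p = 0.0522), no filter (adjusted p = 0.0993) and each of 6 single libraries left out (N2 replicates 1, 2 and 5 and F01D4.5(baf20) replicates 3 to 5), with a median of −0.05 without N2 replicate 2 (adjusted p = 0.256). Over all alternatives the adjusted p ranged from 0.000288 to 0.849 for UDP-glucuronosyltransferases, which lost the call in 9 of 23, from 0.00127 to 0.849 for neuropeptides, which lost it in 8 of 23, and from 0.00801 to 0.849 for pharynx genes.

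In total, 12 of 48 lists passed with the preset correlation, 3 higher and 9 lower, and 0 with an estimated correlation. The estimated correlation had a median of 0.31 over the lists, against the preset 0.01, so members of a list were far from independent. fry, which asks whether the members of a list move on balance one way, also called 0 lists (lowest adjusted p = 0.832). No list held a gene changed over all genes tested. With N2 replicate 5 left out 2 lists passed, with F01D4.5(baf20) replicate 3 left out 3, and with F01D4.5(baf20) replicate 5 left out 19. Without both libraries numbered 5, 9 of the 12 lists passed at the preset correlation and 0 with an estimated correlation.

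The other 36 lists did not pass (lowest camera adjusted p = 0.0787). Germline and meiosis genes were positive in 19 of 22 cases, with a median of 0.05 (camera adjusted p = 0.0787). The major sperm proteins had a median of 0.09 over 31 genes (adjusted p = 0.190) and the yolk proteins, which provision oocytes, 0.06 over 5 genes (adjusted p = 0.924). Histone genes had a median of 0.11 over 21 genes (adjusted p = 0.187). Stress responses gave medians of −0.27 over 8 cytosolic heat shock genes (adjusted p = 0.190), 0.07 over 9 genes of the mitochondrial unfolded protein response (adjusted p = 0.808) and −0.11 over 18 genes of the intracellular pathogen response (adjusted p = 0.187). The 12 protein-coding genes of the mitochondrial genome had a median of 0.07 (adjusted p = 0.730), and 36 nuclear-encoded respiratory chain genes −0.03 (adjusted p = 0.449). In the abu pharyngeal cuticle family the median was 0.55 over 8 genes while the set test pointed down (adjusted p = 0.190). The camera adjusted p of each of these lists was computed with the preset correlation.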

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

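All tests of explanations in this part were chosen after the result was seen. In each group of 5 libraries, the highest or lowest library was compared with the others by the ratio of its gap to the range. Of 210 such groups (library totals, named genes and list means), 35 exceeded the 95% limit, where chance would give about 10.5. All 35 concerned a library numbered 5, 17 in N2 and 18 in F01D4.5(baf20), and 33 were on the high side.

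Cuticle collagen genes stood out in N2 replicate 5, with 118.7 CPM for bli-1, 329 CPM for bli-2, 962 CPM for col-38, 46.0 CPM for dpy-2, 40.8 CPM for dpy-7, 48.6 CPM for dpy-8 and 26.8 CPM for col-176. F01D4.5(baf20) replicate 5 likewise had 51.5 CPM for bli-1, 146 CPM for bli-2, 545 CPM for col-38, 11.5 CPM for dpy-7, 18.9 CPM for dpy-8 and 269.9 CPM for col-92. In the other 4 libraries of each strain, col-38 lay between 23.3 and 168 CPM in N2 and between 17.1 and 50.6 CPM in F01D4.5(baf20). Moulting genes showed the same, with 91.7 CPM for mlt-10, 97.3 CPM for noah-2, 116 CPM for qua-1 and 188 CPM for mlt-8 in N2 replicate 5. In F01D4.5(baf20) replicate 5 noah-2 was at 48.4 CPM, qua-1 at 68.05 CPM and mlt-8 at 102 CPM. On the low side were pph-7 in N2 replicate 5 (17.1 CPM) and the neuropeptide gene nlp-26 in F01D4.5(baf20) replicate 5 (61.8 CPM).

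Several list means, in log2 CPM, were also high in a library numbered 5. In F01D4.5(baf20) replicate 5 these were the col family (6.99), hedgehog-related and patched-related genes (4.72), the ER unfolded protein response (5.92), cytochrome P450 genes (3.74), UDP-glucuronosyltransferases (4.39), C-type lectins (3.96), the propionate shunt and methionine cycle (6.24) and the metal response (5.48). In N2 replicate 5 they were cytochrome P450 genes (3.85), glutathione S-transferases (3.88), lysozymes and antimicrobial peptides (5.17), fatty acid desaturation, elongation and lipid binding (6.56) and the hypoxia response (6.19).

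Of the 12 lists past the set test in the comparison of strains, 9 still passed at the preset correlation without both libraries numbered 5 and 3 did not, while 0 passed in that fit with an estimated correlation. In the 100 splits drawn, 60 gave at least 12 lists, and the highest other split gave 32. Most of these 60 kept both libraries numbered 5 on one side, unlike the split by strain. Splits that set them apart also reached 12 in several cases, with up to 25 lists, so chance cannot be excluded for this count. A candidate explanation is a spread of developmental stage among all libraries of each strain. The first axis of variation within strains held 60.1% of that variance, the strain means differed by 17.4 on it against SDs of 41.5 and 43.8, and all 12 of the 12 lists moved in the direction that this difference gives, the ribosomal list only marginally. The axis was turned to the strain difference and the lists were chosen for differing by strain. The count could thus arise largely by construction and cannot decide for this explanation. The labels do not say what the axis stands for. With 2 surrogate variables in the model 12 lists passed at the preset correlation, but only 5 of them were among the 12 of the comparison without these variables. The furrow collagens were among the 5, with a median of −0.68 in place of −1.27. With an estimated correlation 0 lists passed in that model. An effect of the strain on the rate of development, which the design allows, thus stays open and untested.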

How the results depend on the processing

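The alternatives with surrogate variables, without both libraries numbered 5, with summed libraries, with rows as deposited and without rRNA genes were chosen after seeing the data. The count of 4 higher and 4 lower genes stayed within 1.5 times with DESeq2's size factors, upper-quartile factors, rows as deposited, and without rRNA or yolk, sperm protein and collagen genes. DESeq2's own test gave 17 higher and 16 lower, with 105 adjusted p not given, and 2 surrogate variables gave 47 and 30; both included all 8 genes. Without both libraries numbered 5 there were 9 and 9, including all 8, and with F01D4.5(baf20) replicates 1 and 2 summed 1 and 1. With no filter 2 genes were lower, and set-10, Y17D7C.3 and Y82E9BR.22 lost the call (adjusted p = 0.0715, 0.087 and 0.0564 by edgeR). With at least 5 CPM by unscaled totals in 5 samples 2 were higher, as F57A10.2 and Y71A12B.8 fell below that filter. Leaving out 1 library gave 1 to 8 higher and 1 to 5 lower genes. Apart from the fewer samples in some of these, the cause was not tested.

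F01D4.5 kept its direction in 22 of 22 alternatives and passed in 13, with adjusted p between 2.86e-07 and 0.132. It was lost with replicates 1 and 2 summed (log2 fold change −1.73, adjusted p = 0.132 by edgeR) and in 8 of 10 fits without 1 library, where fewer samples were fitted. Over all 10 such fits the log2 fold change was −1.88 to −1.61. The share of changed genes within 1 Mb never passed (p of 0.0505 or more over 23 alternatives).

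The 12 lists became 0 with an estimated correlation and 0 with fry, and 2 to 19 without 1 library. Among the alternatives set beforehand, single libraries and the replicate block aside, calls at the preset correlation ended with DESeq2's statistics (oocyte and eggshell, hedgehog-related and UDP-glucuronosyltransferase lists), upper-quartile factors (oocyte and eggshell, pharynx), no filter (pharynx, neuropeptides, UDP-glucuronosyltransferases, ribosomal), the filter of 5 CPM (oocyte and eggshell, ribosomal), and removal of yolk, sperm protein and collagen genes (pharynx). The direction of the test turned for the ribosomal list without N2 replicate 5 (median −0.014, the test up, adjusted p = 0.977; −0.117 to −0.014 without 1 library), for sperm formation with 2 surrogate variables (median 0.021, the test down, adjusted p = 0.843) and that of col-38 without N2 replicate 5 (0.13; −3.16 to 0.13 without 1 library). Without N2 replicate 5 the medians of the col family (0.20), hedgehog-related (0.11), neuropeptide (0.06) and UDP-glucuronosyltransferase (0.01) lists also turned positive while their tests still pointed down. Over all alternatives the adjusted p of the ribosomal and sperm formation lists ranged from 0.00204 to 0.982 and from 0.000167 to 0.849. Over the other 55 named genes, 1065 of 1128 values kept direction and side of the threshold, 55 lost the call and 7 gained it. Most of these genes had not passed in the main fit, so that keeping their side of the threshold says little. The losses were those of called genes. set-10 and Y17D7C.3 lost the call in 12 of 21 alternatives each and Y82E9BR.22 in 11 of 21. Y71A12B.8 lost it in 11 of 20 and pph-7 in 9 of 21. T27E7.1 and F57A10.2 lost it in 0.

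Same-numbered samples did not deviate together throughout, with correlations of 0.15, 0.15, 0.00, −0.13 and 0.82 for numbers 1 to 5, and among the N2 libraries replicate 5 alone correlated best with its own number. With the replicate block 3 higher and 3 lower genes passed, 4 of them among the 8. set-10, Y17D7C.3, Y82E9BR.22 and Y71A12B.8 did not (adjusted p = 0.0719 each). With the block 12 lists passed, but not the pharynx (adjusted p = 0.0553) and ribosomal (adjusted p = 0.0988) lists. At this depth and spread, 2-fold changes were recovered in 32% of simulated cases, so many such differences would be missed. The simulation changed 200 genes, while 8 passed in the data. The adjustment is stricter where fewer genes pass, so recovery in the data may be lower than simulated.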

Other observations

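The genes named in the first 2 paragraphs and all tests of explanations in this part were chosen after the values were seen. Without both libraries numbered 5, edgeR called 18 genes, among them end-3, a GATA factor that specifies endoderm, higher by 2.06 on the log2 scale (SE 0.30, adjusted p = 0.0371). The F-box genes fbxa-191 and fbxa-192 were higher by 1.07 (SE 0.165, adjusted p = 0.0394) and 0.70 (SE 0.112, adjusted p = 0.0416). Lower were pgp-1, a P-glycoprotein transporter (−1.33, SE 0.205), eif-2A (−1.01, SE 0.160) and pals-17, of a family linked to the intracellular pathogen response (−0.96, SE 0.151), each with an adjusted p of 0.0394. In DESeq2's test on all libraries, sdc-3, which acts in sex determination and dosage compensation, was higher by 0.66 (SE 0.117, adjusted p = 1.85e-05), and rpl-29 was lower with −0.85 (SE 0.159, adjusted p = 0.000114). None of these 8 genes passed edgeR's test on all 10 libraries with the strain as the only term. With 2 surrogate variables edgeR called eif-2A, sdc-3, fbxa-192, end-3 and fbxa-191 (adjusted p from 0.00617 to 0.0417), but not pgp-1, pals-17 or rpl-29. DESeq2's test on all libraries also called end-3 (adjusted p = 0.0113), fbxa-191 and eif-2A (adjusted p = 0.00606 each), but not fbxa-192, pgp-1 or pals-17. Among the genes that edgeR called only after both libraries numbered 5 were removed, Y11D7A.7 and K07F5.12 had the smallest adjusted p. They were higher by 0.90 (SE 0.109, adjusted p = 0.0116) and 0.78 (SE 0.101, adjusted p = 0.0168). Both were also called by DESeq2 on all libraries (adjusted p = 0.00584 and 6.51e-06) and by edgeR with 2 surrogate variables (adjusted p = 0.00116 and 0.0113).

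With the strain as the only term, none of the 27 other tested genes within 100 kb of Y82E9BR.22 on chromosome III passed (lowest adjusted p = 0.359 by edgeR). Of the 27, 18 were negative, and the mean log2 fold change was −0.30. This region was singled out of 8 and its count was not set against chance on its own. Its 4 genes with an unadjusted p under 0.05 were all negative. These were elc-1, which encodes elongin C (−0.31, SE 0.082, adjusted p = 0.493), Y82E9BR.2 (−0.42, SE 0.162, adjusted p = 0.793), Y82E9BR.3 (−1.13, SE 0.271, adjusted p = 0.411) and lelo-2 (−0.46, SE 0.105, adjusted p = 0.359), all by edgeR. With 2 surrogate variables edgeR called Y82E9BR.2 (−0.53, SE 0.089, adjusted p = 0.025) and lelo-2 (−0.36, SE 0.067, adjusted p = 0.0389), but not elc-1 or Y82E9BR.3. Y82E9BR.3 (1419196 to 1419869) and lelo-2 (1419855 to 1427226) overlap, so that part of their reads cannot be told apart.

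The 8 changed genes form a pattern without a common list or region. In the 100 splits drawn, 3 gave 8 or more genes, the real one included, and 97 gave 0. This share is under 0.05 and argues against chance for this count, without excluding it. Both other splits called more genes than the strains did, 89 and 1653, which points to a structure of the samples; the latter exchanges N2 replicate 1 and F01D4.5(baf20) replicate 5, whose F01D4.5 levels of 14.4 and 2.15 CPM match their labels. A mislabelled library is argued against, since on the genes called in the fit without it (2 to 13 genes) 0 of 10 libraries lay nearer the other strain, and 31 of 34 single values lay nearer their own strain. Sequence differences in the regions of the called genes, such as linked variants of the strain, might lower or raise neighbours too: the neighbours within 100 kb moved with the called gene by a mean of 0.035 on the log2 scale, at the percentile 75.1 of 10000 random sets, which leaves this open. With 2 surrogate variables edgeR called F33H2.3 near set-10 (0.49, adjusted p = 0.013), and Y82E9BR.2 and lelo-2 near Y82E9BR.22. Each moved in the direction of its called gene. For the count of 1 changed gene within 1 Mb of F01D4.5, 3 of the 100 splits gave as many, the highest other split 41. That 1 gene is F01D4.5 itself, which defines the window, so this comparison cannot tell about its neighbours.

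Among genes counted in several transcript rows, 30 were lower and 11 higher at an unadjusted p under 0.01, against 40 lower and 83 higher for genes with 1 row. The log2 odds ratio was 2.45, with a small constant added to each count. Over the 164 genes with the smallest p in each split, a ratio of that size was met in 4 of the 100 splits, the real one included (highest other 3.096). At the fixed p of 0.01 it was met in 15, of which 11 rest on fewer than 30 genes. A counting shift common to all genes with several rows is argued against, as the medians of the log2 fold changes of 2408 such genes and of 9924 genes with 1 row differed by −0.019. Whether a shift in isoform use or in read coverage could concern these 41 genes alone was not settled.

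The ribosomal RNA gene rrn-3.1 held 303987 counts in N2 replicate 4, against 32101 to 91485 in the other 9 libraries.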
